A study of Mus musculus with 3 samples.

How the data were processed

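Interstitial cells of mouse hearts were released with collagenase II, spun at low speed to remove cardiomyocytes and sorted by flow cytometry into 3 groups on surface Lin28 and surface cKit. The groups were Lin28-negative cKit-negative, Lin28-positive cKit-negative and Lin28-positive cKit-positive, with 1 droplet-based 3' single-cell library (10x Chromium) per group. The submitters' processing notes name Cell Ranger, without a version, the mouse genome build mm10, and Seurat 4.0.2. The number, age and sex of the animals and the filters on cells are not given in the sources used here. In the values every cell has at least 500 UMIs (unique molecular identifiers, each counting 1 captured transcript) and at most 9.99% mitochondrial UMIs.

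The deposited tables hold natural log (ln) values, ln(1 + 10000 x UMIs of the gene / UMIs of the cell), with genes in lines and cells in columns. After the log was undone each cell summed to 10000, and division by the smallest value of a cell gave whole numbers for 100% of the values within 0.01, so whole UMI counts were recovered for every cell and used throughout. The plan had assumed tables of counts, and its methods were kept on the recovered counts. Lin28a and Lin28b transcripts were not analysed here.

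Cells needed at least 200 genes and at most 20% mitochondrial UMIs, a filter that removed no cell. The 3976, 681 and 1176 cells of the 3 libraries, in the order above, were clustered together with scanpy 1.11.5 (Leiden clustering by leidenalg 0.10.2, 2000 variable genes, 30 principal components, 15 neighbours, resolution 1). Kit was left out of the clustering genes because the sort selected on it, and libraries were not integrated because library and group coincide. Clusters were named from marker genes of 19 cell types fixed before the data were examined, as were the gene lists, the comparisons, the rule for named genes and the first set of alternatives. A cluster stayed unnamed where it had weak or fewer than 3 markers of its best type, strong markers of a second type, leading genes of another type, or low depth with no marker of its type among its 10 leading genes, which left 8.07%, 7.93% and 5.44% of the cells unnamed. The doublet caller Scrublet, as implemented in scanpy, marked 21 of 5833 cells (0.360%). By library it marked 0.126%, 1.32% and 0.595%, against expected shares of 3.18%, 0.545% and 0.941%. It was not counted as having worked, since it marked far fewer than expected in the largest library, so no cell was removed as a doublet. An alternative took away the 5% of cells with the highest doublet scores, 199, 34 and 59 cells.

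UMIs were summed over the cells of a library, or over the cells of a class within a library, and expressed as CPM, the standard scaling of counts to a common library total. A class was compared where each library had at least 50 of its cells, which admitted endothelial-like cells in every pair and macrophage-like cells in the pair of Lin28-positive libraries. Levels carry exact Poisson 95% intervals, ratios exact conditional binomial 95% intervals, and shares of cells exact Clopper-Pearson 95% intervals (scipy 1.17.1). With 1 library per group there is no replicate and no test, and every interval covers counting error only. Where a library held fewer than 3 UMIs of a gene, ratios for choosing named genes were taken against 3, and a ratio against 0 UMIs is given as a lower bound. Shares of cells with a UMI and genes per cell were also computed after each cell was thinned to 1000 UMIs, with shallower cells left out.

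Of a gene list, members with at least 20 UMIs in the pair were measured, and lists with fewer than 5 such members were left out. A member is called higher or lower when its ratio is at least 1.5 and its interval excludes 1, and otherwise neither. The median log2 ratio of a list is given with its counting interval and its percentile among 10000 random lists of the same size matched on expression in 20 bins, which describes the list and is not a test. There were 31 gene lists and the 19 marker lists. The named genes are Kit, Cdkn1a, Cdkn2a, Glb1, Lmnb1, G3bp1 and Tia1 whatever their values, and in each pair genes among the 8 with the largest ratio in each direction (5 within a class). Those needed at least 100 CPM and 50 UMIs in the higher library. Mitochondrial, ribosomal protein, haemoglobin and Gm or Rik genes were passed over, and of each list described 2 to 4 members with the largest ratios are named. Other genes in the closing observations were chosen after their values were seen. Positions are those of GENCODE vM21 on mm10.

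Alternatives covered the scaling (TMM, in a Python implementation written for this work, and totals without mitochondrial, ribosomal protein and haemoglobin genes), means over cells in place of sums, with and without pseudocounts of 0.01, 0.1 and 1, the filters on cells and on list members, the clustering settings, and equal weight for each class where 2 classes were compared. After the data were seen, 6 alternatives were added: subtraction of free RNA at the share seen in the class or in the largest endothelial-like cluster, the largest endothelial-like cluster alone, removal of the highest doublet scores, and removal of the cell with the most UMIs of a proliferation list, within endothelial-like cells or the whole library. Free RNA, which leaks from broken cells into all droplets, was measured as the level of another class's markers relative to their level in the whole library. A gene that its subtraction left with at most 3 UMIs in either library was counted as used up and left out. The method was tested on simulated data built from the endothelial-like cells: intervals covered the set ratio for 95.7% of 6574 genes, 0.974% of unchanged genes were called, and 47.0%, 96.9% and 100% of genes changed by 1.5-fold, 2-fold and 4-fold were called. Of lists of 20 unchanged genes 3.80% lay outside the middle 95% of random lists. Both simulated sides were drawn from the pooled profile of the 2 libraries with counting error only. They hold no spread between cells or libraries, so coverage near 95% says nothing about that spread. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.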

Results

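The data describe single cells from the interstitium of the mouse heart, the non-muscle compartment of fibroblasts, vessels and immune cells, sorted on the presence of the RNA-binding protein Lin28 and of the receptor cKit on the cell surface. Lin28 inside the cell blocks maturation of let-7 microRNAs, cKit is the receptor for stem cell factor, and the series relates Lin28 on the surface to cellular stress and senescence. There were 3 libraries without replicates. The Lin28-negative cKit-negative library had 3976 cells and 34031955 UMIs, the Lin28-positive cKit-negative library 681 cells and 7401174 UMIs, and the Lin28-positive cKit-positive library 1176 cells and 10400648 UMIs. Median UMIs per cell were 8630, 9628 and 8068.5 in that order, which is kept below, and median genes per cell 2689.5, 2725 and 2323.5. After thinning to 1000 UMIs, with 107, 68 and 61 shallower cells left out, the median genes per cell were 593, 577 and 562. The median mitochondrial share was 4.90%, 6.11% and 6.46%. All values below are sums of recovered UMIs, given as CPM, and all intervals are 95% intervals that cover counting error only.

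Kit, which encodes cKit (ENSMUSG00000005672.12, mm10 chromosome 5, 75574916 to 75656722, a protein-coding gene), was measured to see how its transcript follows the sort. Kit stood at 3.35 CPM (2.76 to 4.02), 7.43 CPM (5.60 to 9.67) and 7.02 CPM (5.50 to 8.83) in the 3 libraries, so the libraries sorted as cKit-negative and cKit-positive within Lin28-positive cells did not differ in Kit transcript at this depth, with a ratio of 0.944 (0.657 to 1.37). Most Kit UMIs lay in endothelial-like cells, at 18.0, 24.4 and 19.3 CPM, and there in cluster 0, led by the capillary genes Car4 and Timp4, at 40.0 (31.1 to 50.7), 37.4 (27.6 to 49.6) and 28.8 CPM (21.1 to 38.5). The share of endothelial-like cells with a Kit UMI was 6.18%, 14.6% and 9.30% at median depths of 4056, 7815 and 5595 UMIs, and 2.07%, 2.09% and 1.64% after thinning. Cells that should lack Kit gave 0.640% (fibroblast-like, Lin28-negative, median depth 10231.5 UMIs) and 0.610% and 0.155% (macrophage-like, Lin28-positive, median depths 12571.5 and 9588 UMIs). Outside the 3 main classes Kit had 19, 3 and 20 UMIs, at 9.14 (5.50 to 14.3), 6.46 (1.33 to 18.9) and 30.1 CPM (18.4 to 46.4). Of the 20 UMIs, 17 lay in 6 of the 18 cells of the unnamed cluster 13 and 7 in 1 cell. In the Lin28-negative library the same cluster held 14 of the 19 UMIs, in 9 of 32 cells. Its Kit level was 47.2 CPM (25.8 to 79.3) there and 42.6 CPM (24.8 to 68.2) in the cKit-positive library. In the Lin28-positive cKit-negative library it held 0 UMIs in 7 cells. The sort was on surface protein, which the transcript does not measure.

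The 3 libraries held different cell classes. Fibroblast-like cells made up 66.9% (65.4 to 68.3) of the Lin28-negative library, 4.11% (2.75 to 5.89) of the Lin28-positive cKit-negative library and 0.850% (0.409 to 1.56) of the Lin28-positive cKit-positive library. Macrophage-like cells went the other way, with 0.503% (0.308 to 0.776), 48.2% (44.4 to 52.0) and 55.0% (52.1 to 57.9). Endothelial-like cells made up 23.2% (21.9 to 24.6), 35.1% (31.5 to 38.8) and 36.6% (33.8 to 39.4), so there were 0.347, 8.54 and 43 endothelial-like cells per fibroblast-like cell. B cell-like cells came to 0.503%, 1.47% and 0.0850%, lymphatic endothelial-like cells to 0.402%, 2.06% and 1.11%, and cardiomyocyte-like cells to 0.453%, 1.17% and 0.935%.

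The clusters left unnamed took 8.07%, 7.93% and 5.44% of the cells. Some clusters within a class were also unequally filled. Of endothelial-like cells, cluster 0 held 45.4%, 64.9% and 61.6%, cluster 6 (led by the arterial genes Hey1, Sema3g and Gja4) 30.3%, 11.3% and 21.2%, cluster 8 (led by Col13a1 and Lrg1) 13.8%, 20.5% and 10.2%, and cluster 10 (led by Nrg1 and Npr3) 10.5%, 3.35% and 6.98%. Of macrophage-like cells of the Lin28-positive libraries, cluster 4 (led by Fcna, Vsig4 and Folr2) held 59.8% and 49.6%, cluster 7 (led by the inflammatory genes Il1b, Ccl3 and Ccl4) 22.0% and 43.9%, and cluster 11 (shallow cells led by Retnla and Cbr2) 18.3% and 6.49%. With each library clustered alone, 0%, 19.8% and 51.4% of the cells were named macrophage-like (0%, 40.4% and 51.4% when unnamed clusters took their closest class). Endothelial-like cells were 20.9%, 35.8% and 23.2% in that setting (20.9%, 35.8% and 38.1%). With 1000 variable genes, 18.4% and 25% of the Lin28-positive cells were named macrophage-like (48.6% and 55.2%).

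**Figure D1:**
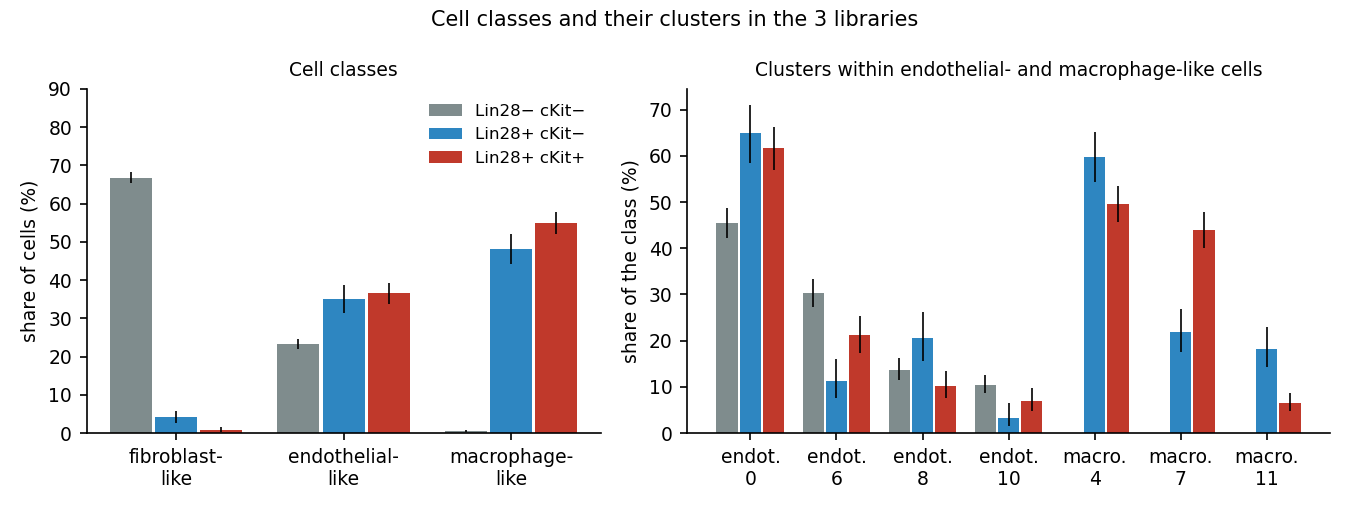
The left panel shows the share of cells (percent) in the 3 main classes per library, and the right panel the share of each class (percent) held by each of its clusters, with bars for the value and lines for exact binomial 95% intervals. Fibroblast-like cells fill 66.9% of the Lin28-negative library, and macrophage-like cells 48.2% and 55.0% of the Lin28-positive libraries (the 20 macrophage-like cells of the Lin28-negative library are left out on the right).

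The first comparison, Lin28-positive cKit-negative against Lin28-negative cKit-negative, asks what surface Lin28 marks among cells without surface cKit. Over the whole library it contrasted macrophage and endothelial transcripts with fibroblast transcripts. All 10 macrophage markers were higher, by a median log2 ratio of 7.94 (7.80 to 8.06), all 10 fibroblast markers were lower (-3.59, -3.70 to -3.54), and 9 of 10 endothelial markers were higher (1.13, 1.08 to 1.18). Cdkn1a, which encodes the cell cycle inhibitor p21, stood at 449 against 139.8 CPM, a ratio of 3.21 (3.07 to 3.36).

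Genes with the largest ratios named the same cell classes. Folr2, a folate receptor of resident macrophages (ENSMUSG00000032725.10, chromosome 7, 101839988 to 101857194), stood at 327 against 0.118 CPM, a ratio of 2784 (1086 to 10227). Cd163, the scavenger receptor for haemoglobin (ENSMUSG00000008845.9, chromosome 6, 124304656 to 124330527), had 874 UMIs against 0, 1339.6-fold higher with the 0 taken as 3 UMIs and at least 1087-fold higher by the counting limit. Cbr2, F13a1, Ms4a7, Fcrls, Ccl12 and Mrc1, all known from macrophages, were higher by between 381-fold (Mrc1) and 1563-fold (Cbr2). Genes lower in the Lin28-positive library were led by Penk, the enkephalin precursor (ENSMUSG00000045573.9, chromosome 4, 4133531 to 4138819), at 4.59 against 175 CPM, 38.0-fold lower (27.2 to 54.9). The dipeptidase gene Dpep1 was 24.1-fold lower (20.9 to 27.9), and Gsta3, the long noncoding RNA Meg3, Hsd11b1, C1qtnf7, Pi16 and Frzb were lower by between 19.7-fold (Frzb) and 22.6-fold (Gsta3). Several of these genes lead the macrophage-like or fibroblast-like clusters, Folr2, Cbr2 and F13a1 among them, and so repeat the class shares.

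Senescence genes did not move together in the whole library. Of the 16 genes known to be raised in senescent cells 6 were higher, 4 lower and 6 neither, with a median log2 ratio of -0.06 (-0.20 to 0.15) and a mean of opposite sign, 0.19. Cdkn2a, which encodes p16 and p19ARF (ENSMUSG00000044303.6, chromosome 4, 89274471 to 89294653), stood at 4.05 against 0.235 CPM from 30 and 8 UMIs, a ratio of 17.2 (7.72 to 43.5), while Dpp4 was lower (3.38 against 16.4 CPM). The 30 Cdkn2a UMIs lay in 14 cells, with 14 UMIs in 9 macrophage-like cells and 1 in an endothelial-like cell. The other UMIs lay in cells outside these 2 classes. The ratio therefore rests on few cells, and the shares of these 2 classes can account for only a part of it. Glb1, the lysosomal beta-galactosidase read out by senescence staining, had a ratio of 0.892 (0.757 to 1.05). Genes known to be lowered in senescent cells counted 5 higher, 1 lower and 4 neither (median 0.66), with Top2a at 21.3 against 2.12 CPM, Hmgb2 at 272 against 135, and the nuclear lamina gene Lmnb1 at 16.1 against 9.20. The senescence-associated secretory list was split, 16 higher, 16 lower and 5 neither, with a median of 0.31 (-0.08 to 0.35). Mmp13 (81.9 against 0.147 CPM), Mmp9 (62.0 against 0.441) and Tnf (389 against 3.85) were among the highest of it, and Mmp13 leads macrophage-like cluster 7. This median was -0.22 when members needed 100 UMIs and -0.09 with means over cells.

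Stress and immune genes differed in size by list. Stress granule genes, whose products gather stalled messenger RNA, counted 3 higher, 0 lower and 27 neither (median 0.28, 0.16 to 0.31, percentile 99.1), with Pabpc1 at 440.5 against 279.5 CPM and G3bp1, a core granule protein gene (ENSMUSG00000018583.5, chromosome 11, 55469685 to 55504838), at 129.98 against 115, but Tia1 at 18.8 against 23.5. NF-kB and inflammation genes counted 13 higher, 2 lower and 5 neither (median 1.52), led by Tnf and by Ccl3 at 944 against 9.40 CPM. All 8 MHC class II presentation genes were higher (median 4.40), among them H2-Aa at 2185 against 76.9 CPM and Ctss at 491 against 8.43. Of 23 interferon response genes 11 were higher and 2 lower (median 0.52), with Cxcl10 at 494 against 24.9 CPM and Isg20 at 6.35 against 29.4. Proliferation genes counted 20 higher, 1 lower and 2 neither (median 1.98), with Cdk1 at 9.86 against 0.588 CPM and Ube2c at 13.1 against 1.06. In the Lin28-positive library 1 endothelial-like cell held 437 of the 2980 UMIs of this list, and the median was also 1.98 without the cell with the most in each library, over 21 members. Of 31 matrix genes 28 were lower (median -3.23), with Dcn at 1111 against 18512 CPM. The let-7 targets and partners of Lin28 counted 4 higher, 5 lower and 9 neither (median 0.15, -0.05 to 0.28), with Arid3a at 22.8 against 2.91 CPM and Igf2bp2 at 0.676 against 5.88.

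Within endothelial-like cells, the class with enough cells on both sides (239 and 923), the same pair can be compared without the class shares. Immediate early genes, genes switched on within minutes of a stimulus, had a median log2 ratio of 0.34 (0.26 to 0.38, percentile 100) with 3 higher, 1 lower and 22 neither, and Zfp36 at 758 against 424 CPM and Btg1 at 379 against 229.9. Heat shock genes had a median of 0.23 (0.15 to 0.26, percentile 99.9) with 1 higher, 0 lower and 19 neither, led by the chaperone gene Hspa1b at 1174 against 574 CPM. Their median was 0.09 (0.04 to 0.17, percentile 95.3) in cluster 0 alone. Cdkn1a (ENSMUSG00000023067.14, chromosome 17, 29090976 to 29100727) stood at 293 CPM (270 to 317) against 207 CPM (193 to 221), a ratio of 1.42 (1.27 to 1.57), and in cluster 0 alone at 284 against 220.1 CPM, a ratio of 1.29 (1.12 to 1.497). Its ratio was 2.04 (1.60 to 2.59) in cluster 6, 1.42 (1.10 to 1.83) in cluster 8 and 0.118 (0.00295 to 0.675) in cluster 10, which held 8 and 97 cells. After thinning, the share of endothelial-like cells with a Cdkn1a UMI was 18.0% (13.3 to 23.5) against 13.7% (11.6 to 16.1).

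Other senescence and stress genes of endothelial-like cells gave mixed values. The raised senescence genes counted 0 higher, 4 lower and 10 neither (median -0.02, -0.31 to 0.17, mean -0.64), the lower members including the stress hormone gene Gdf15 at 0.996 against 12.5 CPM, Dpp4 at 8.47 against 39.4 and Igfbp5. The lowered senescence genes had a median of 0.33 over 10 members (percentile 99.7, and 99.4 among lists matched on length too). Top2a and Mki67 are among them, and the median without the 1 cell rich in proliferation UMIs, described below, is not given here. Cdkn2a stood at 0.498 against 0.480 CPM from 1 and 2 UMIs. Glb1 stood at 10.95 against 10.8 CPM, and Lmnb1 at 17.9 against 12.2 CPM with a ratio of 1.46 (0.928 to 2.29). Stress granule genes counted 2 higher, 0 lower and 27 neither (median 0.13, 0.02 to 0.17, percentile 98.3), with Pabpc4 at 20.4 against 12.2 CPM. This median stood at percentile 96.1 among lists matched on length too, and was 0.09 (-0.02 to 0.18, percentile 97.4) in cluster 0 alone and 0.06 and 0.07 (percentiles 92.6 and 95.01) there with free RNA subtracted at the share of the class and of the cluster. Unfolded protein and integrated stress response genes counted 0 higher, 1 lower and 23 neither (median -0.21, -0.25 to -0.08), with Atf5 at 14.9 against 30.7 CPM and Dnajc3 at 128 against 181. Mitochondrially encoded genes counted 3 higher, 0 lower and 10 neither (median 0.31), with mt-Nd3 at 1655 against 753 CPM. Arterial genes counted 0 higher, 4 lower and 4 neither (median -1.23) and capillary genes 2 higher, 0 lower and 6 neither (median 0.27), with Gja4 at 17.9 against 52.1 CPM and Car4 at 168 against 112, beside the lower share of cluster 6 and the higher share of cluster 0 in Lin28-positive cells.

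Transcripts known from other classes differed in this pair. Fibroblast markers in Lin28-negative endothelial-like cells reached 6.71% of their level in that library (4.75% in cluster 0 and 17.2% in cluster 10), and macrophage markers in Lin28-positive endothelial-like cells 2.66% of theirs. Named by size in this class were Gsn (22.9 against 1548 CPM), Dcn (137 against 1661), Lum, Mgp and Serping1, which were lower, and Lyz2 (182 against 3.84), Cxcl2, Cd74, Slamf1 (134 against 35.5 CPM) and the pericyte marker Rgs5 (294 against 100.4), which were higher. In the Lin28-negative library 4438 of 6915 Dcn UMIs and 6662 of 9239 Mgp UMIs of these cells lay in cluster 10, which also held 3237 CPM of Dcn and 4850 CPM of Mgp in the Lin28-positive library, beside its share of 3.35% against 10.5%. In cluster 0 alone Dcn stood at 10.1 against 756 CPM, Mgp at 45.2 against 552 and Gsn at 24.9 against 1204. Subtraction of free RNA, at the share of the class and at that of cluster 0, left at most 3 UMIs of Gsn, Lyz2, Cxcl2 and Cd74 in 1 or both libraries, and of Serping1 at the share of cluster 0, so these genes have no ratio free of it. The secretory list counted 4 higher, 9 lower and 11 neither (median -0.47, -0.63 to -0.32), with Mmp2 at 0.498 against 37.7 CPM and Serpine2 at 2.49 against 25.7. Its median was -0.34 (-0.56 to -0.18) with free RNA subtracted at the share of the class and -0.57 (-0.76 to -0.35) at the share of cluster 0. In cluster 0 alone it was -0.21 (-0.41 to -0.04) and -0.31 (-0.57 to -0.13) over the 13 and 17 members that the subtraction did not use up. Matrix genes counted 0 higher, 21 lower and 7 neither (median -2.08), with Fbln1 at 0.996 against 50.9 CPM and Col1a2 at 1.99 against 63.4, and had medians of -0.63 (-1.19 to -0.00) and -1.32 (-1.51 to -0.63) after these subtractions. In cluster 0 alone the matrix median was -2.89 (-3.28 to -1.96) over 22 members without subtraction. The subtractions used up 14 and 7 of these members. The 8 and 15 left had medians of 0.07 (-0.13 to 0.28) and -0.08 (-0.39 to 0.08), which do not speak for the members used up. Proliferation genes counted 11 higher, 0 lower and 6 neither (median 1.37), with Cenpf at 29.9 against 0.240 CPM and Ube2c at 27.9 against 0.480; 1 cell held 437 of the 980 UMIs of this list, and the median without it was 0.25.

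**Figure D2:**
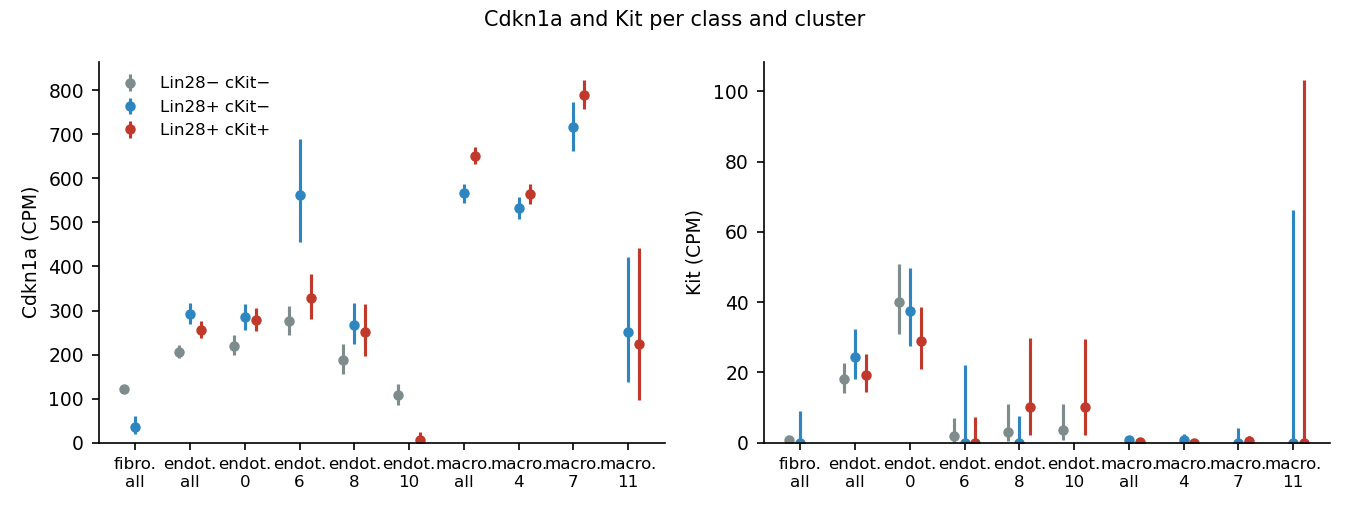
CPM of Cdkn1a (left) and Kit (right) in fibroblast-, endothelial- and macrophage-like cells and in the clusters of the last 2 classes, with points for sums over at least 20 cells, lines for exact Poisson 95% intervals and colours for the 3 libraries. Cdkn1a in endothelial-like cells stands at 207, 293 and 256 CPM, and in the macrophage-like cells of the Lin28-positive libraries at 566 and 652 CPM.

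The second comparison, Lin28-positive cKit-positive against Lin28-positive cKit-negative, asks what surface cKit adds among Lin28-positive cells. Macrophage-like and endothelial-like cells made up most of both libraries. Fibroblast markers were all lower (median log2 ratio -2.40, -2.57 to -2.29), Col1a1 and Dpt most (8.36 against 62.2 and 7.21 against 51.9 CPM), as were 23 of 29 matrix genes (-1.80, and 0.02 with equal weight for macrophage-like and endothelial-like cells), while macrophage markers (-0.01) and endothelial markers (-0.09) had no member past 1.5-fold. MHC class II genes had a median of 0.51 (0.46 to 0.53), and the chemokine gene Ccl4 was 1.75-fold higher (1.73 to 1.78).

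Lower genes of the whole library are known from fibroblasts, B cells, pericytes and lymphatic vessels. Igkc, the immunoglobulin kappa constant region (ENSMUSG00000076609.2, chromosome 6, 70726435 to 70726966), stood at 6.25 against 111 CPM, with 5 of 6 B cell markers lower (median -2.68), and 394 of its 821 UMIs in the cKit-negative library lay in 1 cell. Serping1, Col3a1, Clec3b, Gsn (ENSMUSG00000026879.14, chromosome 2, 35256380 to 35307892), Dcn, Lum and Bgn were 2.74-fold (Bgn) to 8.03-fold (Serping1) lower. Pericyte markers were lower in 7 of 8 (median -0.95), with Rgs5 at 96.9 against 209 CPM, and lymphatic markers in 4 of 6 (median -0.96), with Mmrn1 at 21.0 against 45.5. Higher genes included Ccl4 (ENSMUSG00000018930.3, chromosome 11, 83662584 to 83664683) at 4886 against 2786 CPM, and H2-DMb1, Isg15, Il1b, Cd52 and Cxcl10, higher by 1.60-fold (Cxcl10) to 1.73-fold (H2-DMb1). The histone gene Hist1h2ap stood at 104 against 13.1 CPM, and 5 cells held 839 of its 1082 UMIs. Arterial genes counted 5 higher, 1 lower and 2 neither (median 0.70), with Sema3g at 13.2 against 6.35 CPM and Gja5 at 26 against 4 UMIs.

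Senescence and stress lists of the whole library are read beside the median of all genes, which was itself -0.10 and shifted by 0.113 under TMM scaling. Raised senescence genes counted 1 higher, 0 lower and 15 neither (median 0.02, -0.12 to 0.13), with Dpp4 at 7.50 against 3.38 CPM, Cdkn1a at 529.7 against 449 (ratio 1.18, 1.13 to 1.23) and Cdkn2a at 4.42 against 4.05 (ratio 1.09, 0.674 to 1.79). The lowered senescence genes counted 0 higher, 0 lower and 10 neither (median -0.14), with Cbx5 at 27.8 against 40.8 CPM and Lmnb1 at 21.3 against 16.1. The secretory list counted 2 higher, 7 lower and 26 neither (median -0.14, -0.20 to -0.03), its lower members including Mmp2 at 6.83 against 35.8 CPM and Serpine2 at 5.38 against 24.1. That median was 0.05 with equal weight for the 2 classes, -0.02 under TMM scaling and -0.03 with means over cells. Stress granule genes counted 0 higher, 2 lower and 28 neither (median -0.19, -0.25 to -0.14, percentile 0.330, and -0.08 under TMM scaling), with Usp10 at 11.2 against 18.0 CPM and G3bp1 at 142 against 129.98. Ribosomal protein genes counted 1 higher, 0 lower and 82 neither, with a median of 0.17 (0.16 to 0.18), among them Rpl39l at 1.83 against 0.405 CPM and Rps28 at 1611 against 2118.

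Macrophage-like cells, 647 against 328, carried part of these differences. MHC class II genes, which present extracellular antigen, had a median log2 ratio of 0.32 (0.29 to 0.35, percentile 100), with no member past 1.5-fold, H2-DMb1 at 168 against 115 CPM and Cd74 (ENSMUSG00000024610.15, chromosome 18, 60803848 to 60812652) at 12225 against 9793. The median was 0.25 in cluster 4 and -0.23 in cluster 7 taken alone, so the sign differed between clusters. Of the 24 interferon response genes 6 were higher and 1 lower (median -0.00, mean 0.21), among them the antiviral gene Rsad2 at 21.6 against 5.31 CPM, Ifit2 at 23.4 against 10.4, and Isg15 at 170.4 against 97.0. In cluster 4 the list counted 0 higher, 3 lower and 20 neither (median -0.13). In cluster 7 it counted 5 higher, 1 lower and 17 neither (median 0.20). The Isg15 ratio was 1.23 (1.07 to 1.42) in cluster 4 and 2.44 (1.96 to 3.05) in cluster 7. Stress granule genes counted 0 higher, 1 lower and 29 neither (median -0.22, -0.25 to -0.13, percentile 0.25), and the median was -0.17 in cluster 4 and -0.14 in cluster 7. Hdac6 stood at 1.59 against 3.54 CPM, Caprin1 at 77.3 against 108, G3bp1 at 128 against 126 and Tia1 at 9.95 against 10.2. Ribosomal protein genes had a median of 0.19 (0.19 to 0.21) with all 81 members within 1.5-fold, among them Rpl17 at 2242 against 1726 CPM and Rpl36al at 233 against 309.

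Cdkn1a in macrophage-like cells stood at 652 against 566 CPM, a ratio of 1.15 (1.10 to 1.21), with 1.06 (0.999 to 1.13) in cluster 4 and 1.10 (1.01 to 1.21) in cluster 7. The ratio was 0.963 (0.860 to 1.08) in Xist-alone cells and 1.20 (1.13 to 1.28) in Y-alone cells. The raised senescence genes counted 0 higher, 1 lower and 12 neither (median 0.06, -0.10 to 0.23), with Gdf15 at 126 against 95.4 CPM, Igfbp5 at 1.59 against 3.98, and Cdkn2a at 4.61 against 3.099 (ratio 1.49, 0.772 to 3.02). Their median was 0.09 (percentile 91.3) over 13 members in cluster 4 and -0.38 (percentile 1.3) over 9 members in cluster 7. The sign thus differed between clusters, though in cluster 7 the members counted 1 higher, 0 lower and 8 neither. The lowered genes counted 0 higher, 0 lower and 10 neither (median -0.02), with Lmnb1 at 10.5 against 9.96 CPM and Top2a at 4.61 against 2.21. The secretory genes counted 2 higher, 3 lower and 23 neither (median -0.08, -0.15 to 0.04), with Ccl8 at 18.0 against 31.0 CPM and Il6 at 4.90 against 7.97, and that median was 0.08 with means over cells. Named by size were also Tcim, higher by 1.71-fold, and Ftl1-ps1, AC160336.1 and Rnaset2a, lower by 2.20-fold, 2.03-fold and 1.93-fold. Named by size too were Ccl4 and Il1b (higher) and Retnla and Cbr2 (lower), which are among the leading genes of clusters 7, 4 or 11. Within cluster 4 and cluster 7 the ratio was 1.01 (0.903 to 1.13) and 1.04 (0.968 to 1.12) for Il1b, 1.29 and 1.38 for Ccl4, 0.619 and 0.336 for Retnla, and 0.610 and 0.786 for Cbr2.

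Endothelial-like cells, 430 against 239, differed along vessel type. Arterial genes counted 6 higher, 0 lower and 2 neither (median 1.01, 0.73 to 1.17), with Gja5 at 8.90 against 1.99 CPM and Gja4 at 43.0 against 17.9, beside the share of cluster 6, which was 21.2% against 11.3%. Cdkn1a stood at 256 against 293 CPM, a ratio of 0.873 (0.781 to 0.977), and the ratio was 0.983 (0.854 to 1.13) in cluster 0, 0.941 (0.697 to 1.26) in cluster 8 and 0.585 (0.451 to 0.761) in cluster 6, which held 91 and 27 cells. The share of these cells with a Cdkn1a UMI was 53.3% (48.4 to 58.1) against 57.7% (51.2 to 64.1) at median depths of 5595 and 7815 UMIs, and 23% (19.1 to 27.3) against 18.0% (13.3 to 23.5) after thinning. The raised senescence genes counted 2 higher, 0 lower and 11 neither (median 0.02, -0.14 to 0.24), with Dpp4 at 21.1 against 8.47 CPM, and the secretory genes 6 higher, 0 lower and 15 neither (median 0.31, 0.20 to 0.46), with Il1b at 15.2 against 3.98 CPM and Igfbp6 at 24.8 against 7.47. The secretory median was 0.14 with free RNA subtracted, which used up 3 of the 21 members, and 0.10 in cluster 0 alone. Il1b leads macrophage-like cluster 7, and macrophage markers in these endothelial-like cells reached 4.16% against 2.66% of their library level. The higher Il1b therefore cannot be assigned to endothelial-like cells. Lowered senescence genes counted 0 higher, 2 lower and 8 neither (median -0.29), the lower members being Top2a and Mki67, and had a median of 0.03 in cluster 0 alone. Oxidative stress genes counted 1 higher, 0 lower and 19 neither (median 0.17, 0.10 to 0.27), with the metallothionein gene Mt1 at 189.8 against 100.1 CPM and Gclm at 73.4 against 49.3. This median stood at percentile 97.15 among lists matched on length too, inside their middle 95%. Stress granule genes counted 0 higher, 2 lower and 27 neither (median -0.05, -0.19 to -0.02), with Pabpc4 at 12.6 against 20.4 CPM. Their median stood at percentile 48.5 among lists matched on length too.

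Genes named by size in this class were Mgp (1176 against 279 CPM), Dcn, Cd74, Ccl4 and Plvap (106 against 42.3), which were higher, and Slamf1, AC160336.1, Fmo2, Myadm and the endothelial transcription factor gene Sox18 (185 against 318 CPM), which were lower. Subtraction of free RNA left 0 UMIs of Cd74 and Ccl4 in both libraries. Mgp was lower in cluster 0 alone, at 18.8 against 45.2 CPM, and its level in cluster 10 was 10227 against 4850 CPM in 30 and 8 cells. MHC class II genes had a median of 1.48 over 5 members, with Cd74 at 284 against 102 CPM and H2-Ab1 at 96.0 against 34.4, but macrophage markers in these cells reached 4.16% against 2.66% of their library level, and the subtraction of free RNA used up all 5 members, so the higher level cannot be assigned to these cells. Proliferation genes counted 0 higher, 9 lower and 9 neither (median -0.96), with Ube2c at 1.48 against 27.9 CPM and Cdk1 at 2.22 against 17.9. This median was -0.09 without the cell named above, 0.06 with the highest doublet scores removed and 0.51 in cluster 0 alone, so its direction turned.

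**Figure D3:**
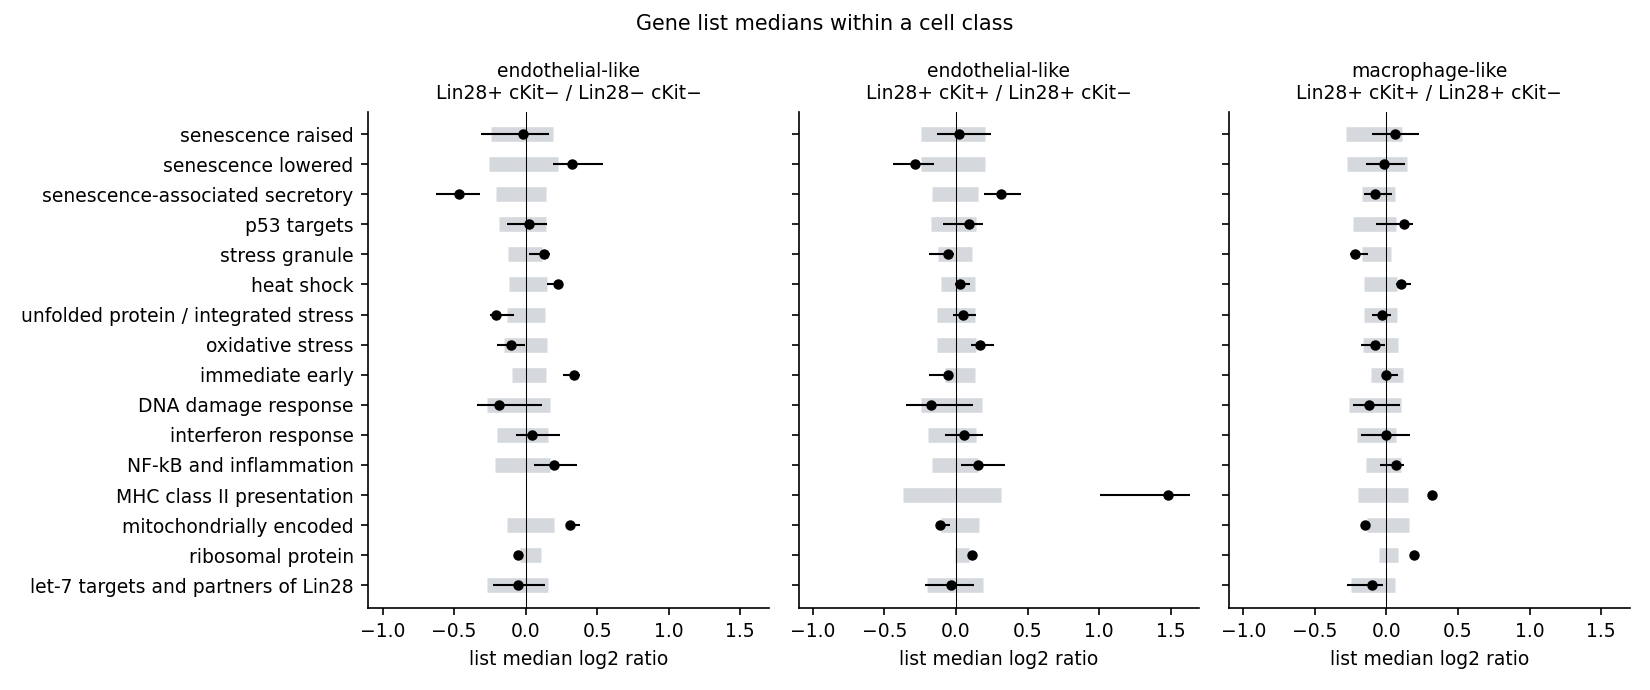
Median log2 ratio of 16 gene lists (horizontal axis) within endothelial-like cells of the first and second pair and macrophage-like cells of the second pair, with points for the median, black lines for its counting 95% interval and grey bars for the middle 95% of 10000 random lists matched on expression. Immediate early genes stand at 0.34 in endothelial-like cells of the first pair, and MHC class II genes at 1.48 and 0.32 in the second pair (not measured in the first).

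The third comparison, Lin28-positive cKit-positive against Lin28-negative cKit-negative, changes both markers and is secondary. Its marker genes moved in the directions of the first pair, with a median log2 ratio of 8.14 for macrophage markers (10 higher, 0 lower and 0 neither), 0.95 for endothelial markers (9 higher, 0 lower and 1 neither) and -6.07 for fibroblast markers (0 higher, 10 lower and 0 neither). Cdkn1a stood at 529.7 against 139.8 CPM (ratio 3.79, 3.64 to 3.94), and in endothelial-like cells at 256 against 207 (ratio 1.24, 1.12 to 1.37). Folr2 led the higher genes with a ratio of 2170.2 (847 to 7971), followed by Cbr2, Ms4a7, Fcrls, Ccl12, F13a1, Lilra5 and Ccl24, the last at 357 (228 to 594). Tnfaip6, a hyaluronan-binding protein gene, had 2 UMIs against 3471, 530.4-fold lower (147 to 4381), and Apod, Sfrp1, Fbln1, Meg3, Dpep1, Serping1 and Htra3 were 102-fold (Htra3) to 228-fold (Apod) lower.

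Senescence genes of the third pair again did not move together. The raised genes counted 6 higher, 6 lower and 4 neither (median 0.04, -0.15 to 0.19), the lowered genes 5 higher, 1 lower and 4 neither (median 0.85), the secretory genes 16 higher, 16 lower and 5 neither (median -0.12, -0.29 to 0.12; mean 0.45) and stress granule genes 1 higher, 2 lower and 27 neither (median 0.08). Cdkn2a stood at 4.42 against 0.235 CPM, Lmnb1 at 21.3 against 9.20, Glb1 at 25.1 against 27.4, the secretory gene Tnf at 459 against 3.85, the stress granule gene Usp10 at 11.2 against 20.8, G3bp1 at 142 against 115 and Tia1 at 18.1 against 23.5. Of the 46 Cdkn2a UMIs of the cKit-positive library, 32 lay in 19 macrophage-like cells and 4 in 4 endothelial-like cells. In endothelial-like cells heat shock genes had a median of 0.27 (0.20 to 0.31) with 0 higher, 0 lower and 20 neither, Hspa1a at 2354 against 1685 CPM and Hspb1 at 3319 against 2452. The p53 targets had a median of 0.15 (-0.03 to 0.24) with 1 higher, 1 lower and 19 neither, and apoptosis genes 0.25 (0.08 to 0.36) with 2 higher, 0 lower and 13 neither, with Phlda3 at 27.8 against 51.6 CPM, Bbc3 at 35.2 against 22.6 and Apaf1 at 15.9 against 8.41. The genes named by size there were Ccl4, Lyz2, C1qa, Cxcl2 and Cd74 (higher) and Gsn, Serping1, Dcn, Igfbp5 and Lum (lower). The subtraction of free RNA, at either share, left at most 3 UMIs of Ccl4, Lyz2, C1qa, Cxcl2, Cd74, Gsn and Serping1 in 1 or both libraries.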

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

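Each value below names the alternative, the value reported and the value under the alternative, and the causes were not tested unless named. The medians of gene lists are log2 ratios, the shares are percent of cells, and libraries are named by Lin28 and cKit sign.

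Shares of cells depended on how clusters were made and named. Macrophage-like cells of the Lin28-positive cKit-negative library (48.2) came to 18.4 with 1000 variable genes, 39.1 with 4000, 38.5 with called doublets removed, 40.2 at resolution 2.0, 43.5 under the strict cell filter and 19.8 with each library clustered alone. At resolution 2.0, with 4000 variable genes, with called doublets removed and under the strict filter, a macrophage-like cluster stayed unnamed for low depth alone. When unnamed clusters took their closest class these values were 48.6, 48.0, 47.5, 49.0, 47.5 and 40.4. Macrophage-like cells of the Lin28-positive cKit-positive library (55.0) came to 25, 50.9, 51.0 and 52.0 under the first 4 of these (55.2, 54.9, 54.7 and 55.8 with the closest class) and to 51.4 with each library clustered alone, and those of the Lin28-negative library (0.503) to 0 in that setting.

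Fibroblast-like cells of the Lin28-negative library (66.9) came to 64.5 with 1000 variable genes, 69.1 with called doublets removed, 69.8 under the strict cell filter, 65.2 with each library clustered alone, and 52.1 with the highest doublet scores removed (66.8 with the closest class). With each library clustered alone those of the Lin28-positive libraries (4.11 and 0.850) came to 6.02 and 0. Endothelial-like cells of the Lin28-negative library (23.2) came to 20.9 with each library clustered alone, 20.6 at resolution 2.0 and 25.4 with the highest doublet scores removed. Those of the cKit-negative Lin28-positive library (35.1) came to 39.7 under the strict filter and 39.1 with the highest doublet scores removed. Those of the cKit-positive library (36.6) came to 39.9 and 41.5 in the same settings and to 23.2 with each library clustered alone (38.1 with the closest class).

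Whole-library medians of the first pair follow. The secretory median (0.31) was 0.75 with the larger library drawn down, -0.0893, -0.0892 and -0.0881 with means over cells without a pseudocount and with pseudocounts of 0.01 and 0.1, -0.22 with members of at least 100 UMIs and 0.40 with members of at least 5. The stress granule median (0.28) was 0.0712 with a pseudocount of 1. Equal weight for each class was not run for the first pair or the third pair, where only endothelial-like cells could be compared.

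In the whole libraries of the second pair, under TMM scaling, which moves the median of all genes, the raised senescence median went from 0.02 to 0.14, secretory from -0.14 to -0.0240 and stress granule from -0.19 to -0.0797. The secretory median was 0.0493 with equal weight, -0.0298, -0.0297 and -0.0293 with means over cells without a pseudocount and with pseudocounts of 0.01 and 0.1, and -0.00890 with a pseudocount of 1, where the stress granule median was -0.0564. The matrix median (-1.80) was 0.0231 with equal weight. In the third pair oxidative stress (0.29) was -0.00764, -0.00758, -0.00712 and -0.00211 with means over cells without a pseudocount and with pseudocounts of 0.01, 0.1 and 1.

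In macrophage-like cells the stress granule median (-0.22) was -0.12 under TMM scaling and -0.0576 with a pseudocount of 1. The secretory median (-0.08) was 0.0929 with the highest doublet scores removed, 0.0807 with means over cells, 0.0743 with a pseudocount of 0.01 and 0.0435 with 0.1.

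In endothelial-like cells of the first pair the secretory median (-0.47) was -0.0672 with a pseudocount of 1. In the largest cluster alone the venous and endocardial (-1.15 to 0.000517), activation (-0.82 to 0.0673) and ribosomal protein (-0.05 to 0.0546) medians reversed, and the last was 0.0241, 0.0241, 0.0240 and 0.0228 with means over cells without a pseudocount and with pseudocounts of 0.01, 0.1 and 1.

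In endothelial-like cells of the second pair the secretory median (0.31) was 0.138 with free RNA subtracted at the share of the class and 0.162 at that of the largest cluster, 0.10 in the largest cluster alone, 0.0699 with a pseudocount of 1 and 0.19 with members of at least 100 UMIs. The largest cluster alone reversed lowered senescence genes (-0.29 to 0.0336), proliferation (-0.96 to 0.51) and Mgp (2.07 to -1.26). Proliferation was 0.0565 with the highest doublet scores removed. In the third pair subtraction of free RNA reversed NF-kB and inflammation (0.13 to -0.0541 at the share of the class and to -0.12 at that of the largest cluster). These subtractions used up 5 and 6 of the 20 members, so the medians compare different sets of genes. Subtraction of free RNA used up every measured MHC class II member in the second pair and the third pair. It also used up Cd74, Cxcl2, C1qa, Ccl4 and other genes, which have no value under it.

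Of 72 class shares 27 moved and 45 did not, and of 216 medians of the lists weighed first 28 moved and 188 did not. Of the other list medians 504 moved, 17 reversed and 2222 did neither, and of the named genes 342, 1 and 1030. The share of cells with a Kit UMI moved in all 3 libraries on thinning. Leaving out the filter on cells changed no cell, so it tests nothing and the CPM of Kit per library has no other alternative.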

Other observations

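Sex-chromosome transcripts were mixed in every library, so each held cells of both male and female animals. Cells with Y-linked transcripts alone and cells with Xist alone numbered 2051 and 728 in the Lin28-negative library, 368 and 90 in the Lin28-positive cKit-negative library, and 600 and 174 in the Lin28-positive cKit-positive library. Xist-alone cells were 26.2%, 19.7% and 22.5% of the cells with 1 kind. Cardiac muscle transcripts were low but higher in the Lin28-positive libraries, with Myh6 at 7.05, 17.0 and 21.8 CPM, Tnnt2 at 15.9, 33.1 and 45.3 and Actc1 at 10.6, 35.0 and 32.4, although cardiomyocytes were removed before the sort.

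Single cells carried some large ratios. In the Lin28-positive cKit-negative library 3009 of 3025 Hbb-bs UMIs and 3084 of 3103 Hba-a1 UMIs lay in 1 cell, and Hbb-bs had 0 UMIs in the cKit-positive library. Igkc had 821 UMIs in 16 cells of the former and 65 UMIs in 7 cells of the latter.

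The 3 patterns weighed next were chosen after the results were seen, as were all of the tests, and 6 alternatives were added then. The first is the class composition, macrophage-like and endothelial-like cells in place of fibroblast-like cells among Lin28-positive cells. A different mix of male and female animals could not produce it, because within the cells with Y-linked transcripts alone, and within those with Xist alone, the fibroblast-like share still fell by at least 58.4 points between the Lin28-negative and the Lin28-positive cKit-negative library. Antibody caught by Fc receptors may account for the macrophage part, but transcripts cannot decide this. These cells carried 996 CPM of Fcgr1, Fcgr2b, Fcgr3 and Fcgr4 (967 to 1026). Fcgr1 is among the markers that named the class, so such transcripts were bound to appear in it. The 20 macrophage-like cells of the Lin28-negative library carried 816 CPM (640 to 1026). Binding through Fc receptors and surface Lin28 on macrophages cannot be told apart with transcripts. Fc receptors are an unlikely cause of the endothelial part, where their transcripts reached 1.80% (1.26 to 2.49) of the macrophage level, near the 1.68% that macrophage markers reached in the same cells through free RNA. Sorting again with an isotype control and Fc block, or from animals lacking Fc receptors, would separate these causes.

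The second pattern is Cdkn1a, higher in Lin28-positive cells, where the mix of classes may explain part of the whole-library ratio. Lin28-negative levels weighted by each class's share of UMIs, not of cells, in the Lin28-positive cKit-negative library give 303 CPM. The 2 libraries were observed at 140 and 449 CPM. However, the macrophage-like level in this weighting (369 CPM, 254 to 518) rests on 20 cells and 33 UMIs. A ratio of 1.29 (1.12 to 1.497) remained within the largest endothelial-like cluster and of 1.36 (1.22 to 1.52) in the class after free macrophage RNA was subtracted, but the ratio was 2.04 in cluster 6, 0.118 in cluster 10, 2.89 (2.18 to 3.84) in Xist-alone cells and 1.37 (1.19 to 1.58) in Y-alone cells. Stress during dissociation or sorting is a candidate explanation for what remains, because immediate early genes had a median log2 ratio of 0.34 (0.26 to 0.38, percentile 100) in the same cells, and 0.53 in the largest cluster. In endothelial-like cells of the third pair the Cdkn1a ratio was 1.24 (1.12 to 1.37), and 1.27 (1.11 to 1.46) in the largest cluster. The immediate early median of endothelial-like cells in that pair was only 0.13 (percentile 96.4), so this candidate stays open. A senescence program might also raise Cdkn1a. In endothelial-like cells of the first pair the raised senescence genes had a median of -0.02, and 0.13 (-0.23 to 0.32, percentile 90.1) in the largest cluster alone. Both intervals include 0 and are wide, so they do not settle this. The lowered senescence genes, Top2a and Mki67 among them, had a median of 0.33 (percentile 99.7) in the class. In its Lin28-positive cKit-negative part 1 cell held 437 of the 980 proliferation UMIs, and the median without that cell is not given here. Measuring p21 protein and Cdkn1a in fixed tissue, or after dissociation with a transcription inhibitor, would test these candidates for Cdkn1a.

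The third pattern is a set of differences shared by macrophage-like and endothelial-like cells between the Lin28-positive libraries. Transcript length may contribute a part, since the log2 ratio fell with length in macrophage-like cells (Spearman -0.328 over 7340 genes) and endothelial-like cells (-0.344 over 5516 genes), where genes are not independent replicates. The ratios of the 2 classes correlated at 0.418, and still at 0.327 after regression on length, at 0.371 after free RNA was subtracted and at 0.282 after both. Length was that of the longest annotated transcript of each gene, and free RNA was modelled on the profile of the whole library. A part of either may therefore remain. Neither as corrected here accounts for all of the correlation, and what else the 2 classes share stays open. The stress granule median of macrophage-like cells, -0.22 with 1 of 30 members lower and -0.12 under TMM scaling, may be part of the length trend or not. The list stood at percentile 1.80 among random lists matched on abundance and length, below their middle 95% (-0.216 to -0.0262). Its counting interval, -0.25 to -0.13, reaches into that range, so the question stays open. Repeating the sort with the libraries prepared side by side, with RNA quality measured, would show whether the shared differences belong to cKit or to the preparation.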
